A study of Arabidopsis thaliana with 10 samples.

How the data were processed

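Gene expression was measured with Affymetrix ATH1 arrays in whole shoots of Arabidopsis thaliana that carried the transgene pSHR:SHR-GR in the shr-2 mutant. The deposited values are one MAS5 signal intensity per probe set and array on a linear scale, made with Affymetrix Expression Console 1.1, per the submitters' processing notes. Those notes give neither the background correction nor the scaling target. On each of the 10 arrays the mean without the top and bottom 2% of the values was 500, so the arrays had been brought to a common level before deposition. Detection calls were not used here. Total RNA of 300 ng per sample was extracted with an RNeasy kit and labelled with a 3' IVT Express kit, per the labels' protocols.

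Each array held 22810 probe sets, of which 64 control probe sets were set aside and 22746 were tested. The probe table named 1 gene for 13513 tested probe sets and several genes for 503, and it did not list 8730. The named probe sets covered 13355 genes, of which 147 had 2 or more probe sets and 13286 had a locus. Gene symbols came from the TAIR10.1 reference, from which names and no coordinates were used. Of 407 distinct loci in the gene lists fixed in advance, 53 had a named probe set. No probe set was named for SHR itself, SCR, MGP, NUC, SCL3, CYCD6;1, CCA1, LHY or TOC1, so these genes are not analysed here, and counts of all probe sets include many without a gene name.

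The groups were the control at 0 hr and 3, 6, 12 and 24 hr of 10 µM DEX, each with 2 arrays that the design text calls biological replicates. No mock-treated arrays of the DEX times exist in the series, so time of day, handling, age and DEX itself go with every comparison against 0 hr. The number of arrays limits the precision of each value.

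Signals were transformed as log2 of the signal plus 16 and fitted with limma 3.58.1 in R 4.3.3, with one mean per group over all 10 arrays, moderated variances with an intensity trend and no further normalization. The fit had 5 residual and 5.86 prior degrees of freedom. Each DEX time was compared with 0 hr and each time with the one before it, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets within a comparison and a threshold of 0.05. A moderated F test over the 4 DEX times gave the probe sets changed at any time. The SE printed beside a log2 fold change comes from this fit, and the SD beside a mean signal comes from the 2 arrays of the group. An exact permutation test of 2 arrays against 2 cannot give a p below 0.33, so no such test was used. The procedure was tested on simulated data with 200 of 22746 probe sets changed in 1 DEX group of 2 arrays against 2 control arrays. The changed ones were drawn from above the 30th percentile of mean signal, so recovery among dimmer probe sets was not examined. Over 5 simulations it recovered 90.6% of changes of 1 and 100% of changes of 2 on the log2 scale, 5% of the calls were wrong, and an unchanged group gave 0 calls. The simulated noise was normal and independent between probe sets, with the variances of the fit, which is close to the model of limma. The share of wrong calls on real arrays, with correlated probe sets or array effects, was therefore not examined.

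The comparisons, the tests, the rule for naming genes, 25 gene lists and the alternatives to the fit were chosen before the data were examined. At each DEX time the rule named the measured members of a list of root targets of SHR. It further named the 8 largest rises and the 8 largest falls among called probe sets of 1 gene, with a mean above the 30th percentile of all probe sets and both DEX arrays on the same side of both control arrays. From each list it named up to 4 called members with the largest changes, or up to 2 if none was called, and for successive times it named 3 rises and 3 falls. Genes that made up a count of 5 or fewer, such as MGL, psbH and AtLEA4-1 at 6 hr, and examples of genes called at all times or in opposite directions were named after their values were seen. A gene with several probe sets was represented by the one with the highest mean. A signal below 43.4, the 30th percentile, is called near background, and the size of a change from or to such a signal depends on the offset added before the logarithm.

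Because few members of those lists had a named probe set, 27 further lists were built from the gene names in the probe table, after those names were seen and before any groups were compared. Lists with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, separately for the fixed and the further lists, with adjustment over lists and 4 times. Camera with an estimated correlation and limma's fry were run beside it, which for the further lists was decided after seeing the data. The former tests on the 5 residual degrees of freedom of the fit, so its p can rise without a larger correlation. Neither camera nor fry adjusts for the lack of mock-treated arrays.

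Alternatives to the fit were offsets of 1 and 64, quantile normalization, scaling to a common median, leaving out the lowest 30% or 50% of the probe sets, variance moderation without the trend or with a robust trend, array weights, a replicate block, a fit of only the 4 arrays compared, a log2 fold change of at least 1, and leaving out each array in turn. Of the 10 fits without 1 array, 4 left out an array of a given comparison. The rest kept its fold changes and altered only the estimate of the spread, so a call lost in 4 of the 10 may rest on every array compared. For the overlaps between times, 20 simulations with no effect and 2 shared control arrays gave the correlations and covariances of fold changes that shared controls alone produce. A further 20 gave the overlap and the share with the same sign among their top probe sets, as many per time and direction as were called.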

Results

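Transcripts were measured in whole shoots at 10 days after germination (DAG) of shr-2 plants that carried SHORT-ROOT fused to the glucocorticoid receptor under the SHORT-ROOT promoter. SHORT-ROOT (SHR) is a GRAS-family transcription factor that directs radial patterning of the root, and the fusion moves into the nucleus when dexamethasone (DEX) is given. Shoots were sampled at 0 hr as the control and after 3, 6, 12 and 24 hr of 10 µM DEX, with 2 biological replicates per time and 10 arrays in all. DEX was applied at 10 DAG, or at 9 DAG for the 24 hr treatment, to plants kept at 22 °C with 16 h of light and 8 h of dark. Median signals per array ran from 181.8 to 191.7, and the correlation across probe sets between the 2 replicates of a group ran from 0.9858 to 0.9909.

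The first principal component held 21.1% of the variance and the second nearly as much. The 3 hr arrays lay farthest from the controls on the first component, at 28 and 29.4 against -21.9 and -21.3. The 6 hr arrays lay at -30.6 and -24.9 on the second component, where the controls lay at 15.1 and 18.4. The 24 hr arrays, at -19.2 and -14.4 on the first component, were nearest to the controls. On the 2 components 12 hr replicate 2, at -6.6 and -4.6, lay nearer to 24 hr replicate 2, at -14.4 and -7.3, than to its partner at -3.9 and -13. Across probe sets 12 hr replicate 1 and 24 hr replicate 2 each had a correlation of 0.9906 with an array of another group, against 0.99 and 0.9887 with their partners.

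**Figure D1:**
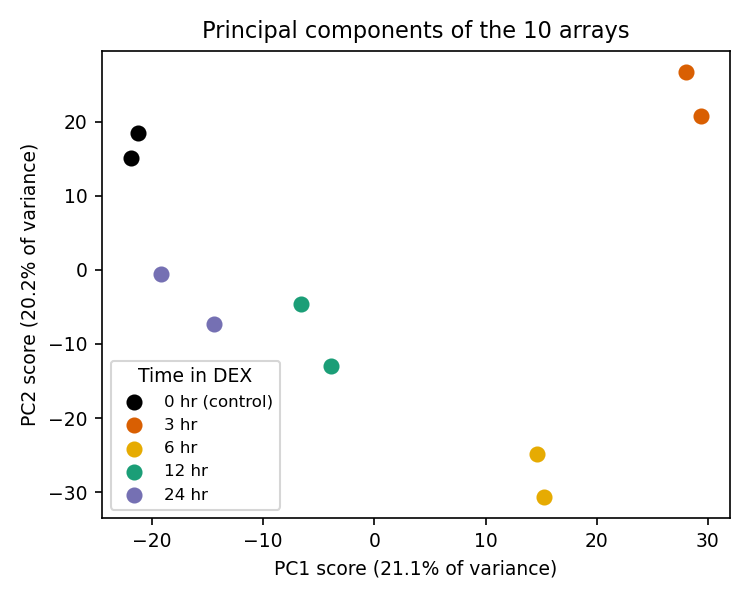
Scores of the 10 arrays on the first principal component (x axis, 21.1% of the variance) and the second (y axis), 1 point per array, coloured by hours of DEX. The 24 hr arrays lie nearer to the controls than the 3 hr arrays do on the first component.

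At any time of DEX, 2992 of 22746 probe sets (13.2%) changed by limma's moderated F test. The count was 1940 without 3 hr replicate 1 and 1981 without 3 hr replicate 2. By time, 1870 probe sets were called at 3 hr, 2129 at 6 hr, 364 at 12 hr and 218 at 24 hr. The higher ones made up 47.6% of the calls at 3 hr, 55.2% at 6 hr, 79.4% at 12 hr and 74.8% at 24 hr. The median log2 fold change of all probe sets was -0.03 at 3 hr, -0.06 at 6 hr, -0.03 at 12 hr and -0.03 at 24 hr.

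**Figure D2:**
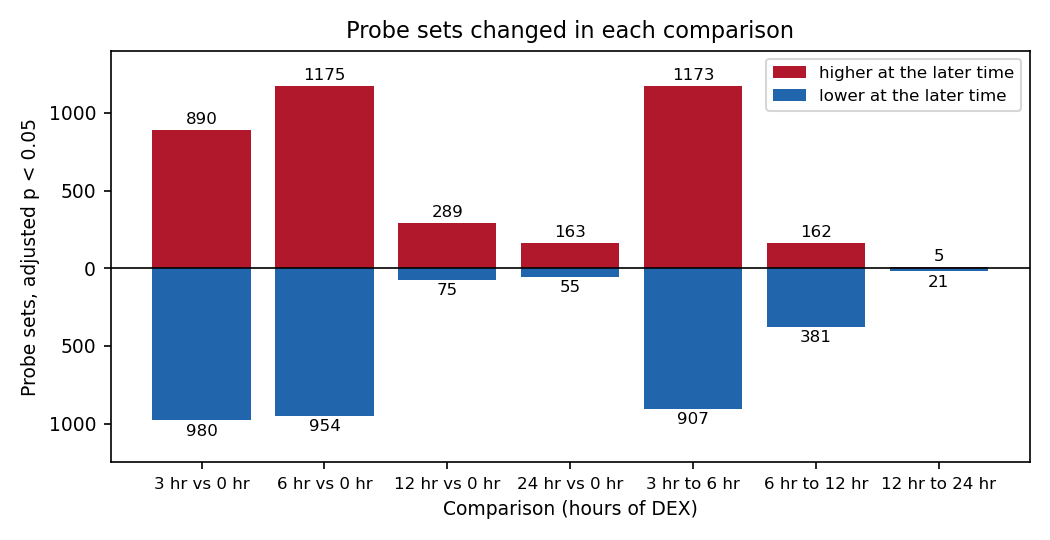
Number of probe sets (y axis) called higher or lower at adjusted p below 0.05 in each comparison (x axis). Calls were most frequent at 6 hr (1175 higher, 954 lower) and least frequent from 12 to 24 hr (5 higher, 21 lower).

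The first comparison asked which transcripts differed after 3 hr of DEX. COR15A, a cold-regulated protein of the chloroplast, rose 14.9-fold, from a signal of 1010 ± 58.4 to 15300 ± 1870 (SD, n = 2 arrays each; log2 fold change 3.89, SE 0.15, adjusted p = 1.23e-07). LTI30, a dehydrin, rose 11.7-fold, from 105 ± 15.3 to 1400 ± 134 (SD, n = 2 each). The largest rise among the named genes was that of AT3G28220, which encodes a TRAF-like protein, at 23.4-fold (log2 fold change 4.55, SE 0.17). JRG21, AT2G38240 and AT5G05600, 2-oxoglutarate-dependent oxygenases that hydroxylate jasmonic acid, rose 13.4-fold, 14.2-fold and 8.95-fold. The thionin gene AT1G66100 rose 12.1-fold and the GDSL lipase gene AT1G54020 rose 8.63-fold.

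The falls at 3 hr were smaller. AT1G19960 dropped from 2530 ± 138 to 409 ± 37.8 (SD, n = 2 each; log2 fold change -2.58, SE 0.08, adjusted p = 3.15e-08). NRT2.5, a high-affinity nitrate transporter, fell by 1.69 on the log2 scale (SE 0.19), and the other named falls were AT4G19430 at -2.1, TBL36 at -1.53, CYP71B22 at -1.49 and AT3G27400 at -1.48. AT4G16000 and AT4G11900 fell to signals of 3.55 and 28.3, near background, from 62.8 and 129. In all, 890 probe sets were higher and 980 lower at 3 hr, 161 and 106 of them by at least 2-fold. Scaling the arrays to a common median gave 1156 higher and 689 lower. The total of 1870 was 866 without control replicate 1, 967 without control replicate 2, 1096 without 3 hr replicate 1 and 969 without 3 hr replicate 2.

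Of 17 measured genes of the further list for cold and dehydration, 6 rose at 3 hr, 0 fell and 11 did not pass. COR15B, a close relative of COR15A, rose by 2.12 (SE 0.13) and the dehydrin COR47 by 0.85 (SE 0.08) on the log2 scale. The list shifted upwards by camera (adjusted p = 0.000204), with adjusted p = 0.129 with an estimated correlation. Of 12 jasmonate output genes, 4 rose and 8 did not pass, among the former THI2.1, a thionin, at 1.09 (SE 0.2), and BSMT1, a methyltransferase that makes methyl salicylate, at 1.89 (SE 0.26), whose signals were low. The jasmonate list shifted upwards (adjusted p = 0.000459, and adjusted p = 0.142 with an estimated correlation). Of 13 unfolded-protein response genes, 3 rose, CRT1b by 0.72, ATERDJ3B by 0.61 and OS9 by 0.36, and 10 did not pass. Calreticulin CRT1b and the J-domain protein ATERDJ3B are chaperones of the endoplasmic reticulum. That list shifted upwards as well (adjusted p = 0.0136, and adjusted p = 0.149 with an estimated correlation). Only 4 of the 10 fits without 1 array left out an array of this comparison. Without 1 array OS9 lost its call in 4 of the 10 fits and THI2.1 in 2.

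Of 43 plastid-encoded photosynthesis genes 10 fell at 3 hr, 0 rose and 33 did not pass, with petA, a cytochrome f gene, at -0.85 (SE 0.1), psaC at -0.75 (SE 0.17), psaJ at -0.68 (SE 0.09) and psbK at -0.67 (SE 0.11) on the log2 scale. The downward shift had adjusted p = 7.87e-05, and adjusted p = 0.142 with an estimated correlation. The control probe sets for 5S and 25S rRNA stood at -0.15 and -0.19 at 3 hr (adjusted p = 0.849 and 0.77), with a 25S signal of 4570 on 3 hr replicate 2 against 5960 and 5830 on the control arrays. Of 19 plastid genes of transcription and translation 6 fell, among them rpl16 at -0.61 and rps18 at -0.6 (adjusted p of the list = 0.000347, and adjusted p = 0.142 with an estimated correlation). Of 11 flavonoid genes 4 fell and 7 did not pass, with DFR, dihydroflavonol reductase, at -0.68 (SE 0.07) and CHIL at -0.38 (SE 0.08). The flavonoid list shifted downwards (adjusted p = 0.0136, and adjusted p = 0.149 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0823) and without 3 hr replicate 1 (adjusted p = 0.0571). Of the 10 fits without 1 array, rpl16 lost its call in 4, psaC and CHIL in 3 and rps18 in 2.

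The second comparison asked which transcripts differed after 6 hr. AT3G15450, an aluminium-induced-like protein, rose 10.3-fold, from 606 ± 43.6 to 6430 ± 613 (SD, n = 2 each; log2 fold change 3.37, SE 0.11, adjusted p = 3.24e-08). AT2G20670 rose 9.89-fold and AT1G23390, a Kelch-repeat F-box gene, 6.26-fold, and AT1G33055 rose from a signal of 9.14, near background, to 142. JRG21 was 11.8-fold above the control, AT3G28220 7.67-fold, AT5G05600 6.85-fold and AT1G66100 6.15-fold. AT3G44450, known as BIC2 and an inhibitor of the cryptochrome blue-light receptors, fell from 785 ± 25.1 to 219 ± 2.65 (SD, n = 2 each; log2 fold change -1.77, SE 0.09). ASPGB1, an asparaginase, fell by 1.4 (SE 0.15) on the log2 scale. EXPA18, an expansin of root hairs, and AT2G18820 fell to signals of 20.4 and 23.7, near background, from 83.9 and 89.5, and AT2G18820 lost its call in 3 of the 10 fits without 1 array. Other named falls were AT2G15020 at -1.57, AT2G27420 at -1.37, AT5G42760 at -1.28 and the glutaredoxin gene AT4G33040 at -1.25.

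At 6 hr 1175 probe sets were higher and 954 lower, 298 and 97 of them by at least 2-fold. The total of 2129 was 1097 without control replicate 1, 1136 without control replicate 2, 989 without 6 hr replicate 1 and 1174 without 6 hr replicate 2.

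**Figure D3:**
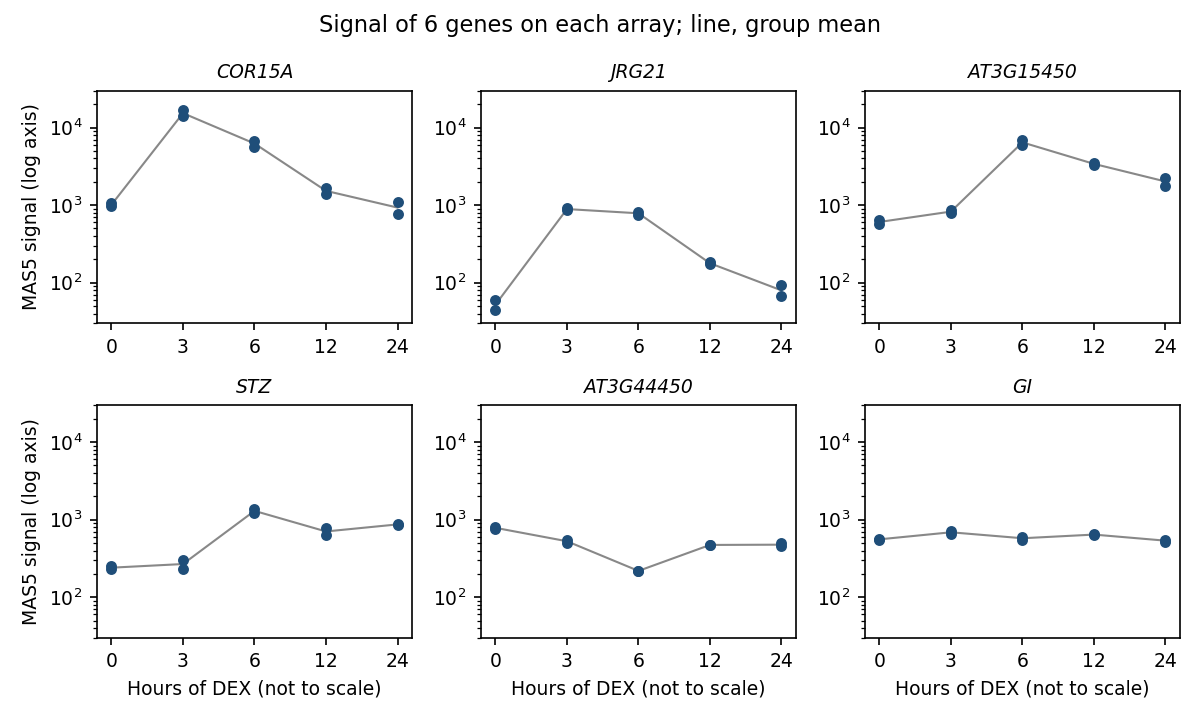
MAS5 signal (y axis, log scale) of 6 genes against hours of DEX (x axis, not to scale), with 1 point per array and a line through the group means. COR15A peaked at 3 hr at a mean of 15300, AT3G15450 at 6 hr at a mean of 6430, and GI, which did not pass over all probe sets at any time, had a largest log2 fold change of 0.29.

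Early defence and touch genes were the list with the smallest p of the 27 further lists at 6 hr. Of its 24 measured genes 10 rose, 0 fell and 14 did not pass (adjusted p = 7.19e-09, and adjusted p = 0.114 with an estimated correlation). AT4G27280, a calcium-binding EF-hand protein, rose by 2.56 (SE 0.12), STZ, a zinc-finger repressor, by 2.36 (SE 0.13), the calmodulin-like gene CML38 by 1.96 (SE 0.2), from a control signal of 32.4 near background, and the transcription factor gene WRKY53 by 1.51 (SE 0.16) on the log2 scale. At 3 hr 2 of the 24, CML38 and the dim PUB22, had passed, each of which lost its call in 3 of the 10 fits without 1 array, and the sign of the list median at 3 hr depended on scaling, at -0.04 as deposited, 0.02 after quantile normalization and 0.01 with a common median. Of 14 genes for darkness and sugar starvation 5 rose, 1 fell and 8 did not pass at 6 hr (adjusted p = 0.000204, and adjusted p = 0.129 with an estimated correlation). AKINBETA1, a regulatory subunit of the SnRK1 kinase, rose by 1.21 (SE 0.11) and AT3G15630 by 1.39 (SE 0.11), while MGL, methionine gamma-lyase, fell by 0.47. GAT1_2.1 rose by 2.19 (SE 0.28) on its brighter probe set, from a control signal of 25.4 near background, whereas its other probe set stood at -0.22 and did not pass.

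Cold and dehydration genes still shifted upwards at 6 hr, with 7 of 17 higher, 1 lower (AtLEA4-1, at -0.9) and 9 that did not pass (adjusted p = 7e-04, and adjusted p = 0.132 with an estimated correlation). COR15A was 2.59 (SE 0.15) and LTI30 2.1 (SE 0.16) above the control on the log2 scale. Jasmonate output genes numbered 3 of 12 higher and 9 that did not pass, and shifted upwards (adjusted p = 0.000204, and adjusted p = 0.134 with an estimated correlation). OPCL1, an enzyme of jasmonate synthesis, rose by 0.73 (SE 0.12). Of 58 glycosyltransferase and glutathione transferase genes 10 rose and 48 did not pass, with UGT73B1 at 1.53 (SE 0.16) and UGT85A2 at 0.9 (SE 0.12). The list call (adjusted p = 0.0292, and adjusted p = 0.248 with an estimated correlation) was lost without control replicate 2 (adjusted p = 0.107) and without 6 hr replicate 2 (adjusted p = 0.0765).

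Of 43 plastid-encoded photosynthesis genes 16 fell, 1 rose and 26 did not pass at 6 hr (adjusted p = 0.000204, and adjusted p = 0.149 with an estimated correlation). The photosystem gene psbN fell by 1.19 (SE 0.21), ndhG of the plastid NDH complex by 0.97 (SE 0.19) and petN of the cytochrome b6f complex by 0.97 (SE 0.11) on the log2 scale, and psbH was the gene that rose, by 0.43. Of 21 nuclear photosynthesis genes 4 fell, 1 rose and 16 did not pass, with the antenna gene LHCB4.3 at -0.77 (SE 0.09) and PORB, a protochlorophyllide reductase, at 0.6 (SE 0.09). The nuclear list shifted downwards (adjusted p = 0.0094, and adjusted p = 0.247 with an estimated correlation), but not after quantile normalization (adjusted p = 0.413) or without control replicate 2 (adjusted p = 0.0759). Plastid genes of transcription and translation had a median of -0.04 at 6 hr, which became 0.03 after quantile normalization, and 2 of the 19 fell, rps14 by 1.25 and rpl20 by 0.71. The control probe set for 5S rRNA stood at -0.45 at 6 hr (adjusted p = 0.168) and that for 25S rRNA at 0. Without 1 array psbN and ndhG each lost the call in 2 of the 10 fits.

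**Figure D4:**
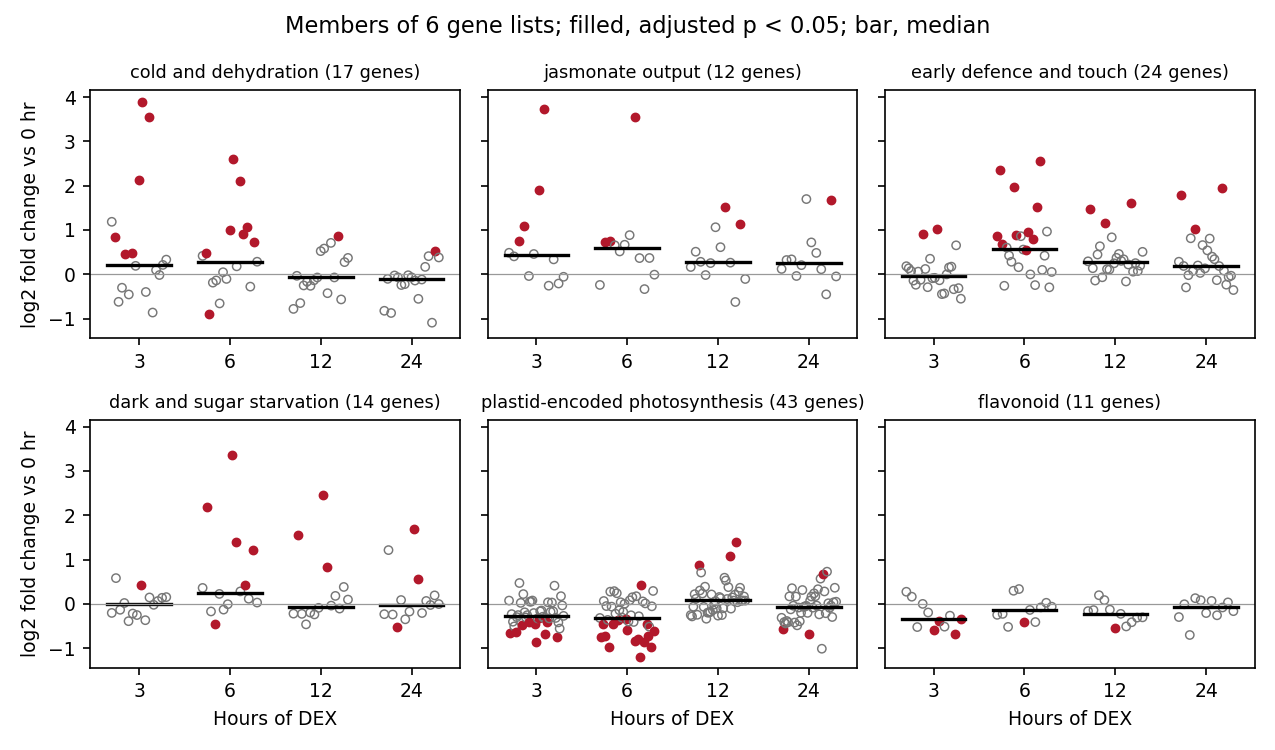
Log2 fold change against 0 hr (y axis) of each measured member of 6 further gene lists at 3, 6, 12 and 24 hr of DEX (x axis), with filled points for adjusted p below 0.05 and a bar at the median. Early defence and touch genes have a median of 0.58 at 6 hr and plastid-encoded photosynthesis genes one of -0.31, while the sign of the former at 3 hr (-0.04) depends on how the arrays are scaled.

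After 12 hr the calls were fewer and mostly higher, with 289 probe sets higher and 75 lower, 88 and 10 of them by at least 2-fold. AT2G20670 was 5.76-fold, AT3G15450 5.49-fold and AT1G23390 4.89-fold above the control. AT4G27280 rose from 423 ± 64.4 to 1320 ± 71.6 (SD, n = 2 each; log2 fold change 1.61, SE 0.12, adjusted p = 5.44e-05), and AT4G16447 rose by 1.84 on the log2 scale. AT1G33055, ZCF37 and AT1G04660 rose to signals of 115, 114 and 63.7 from control signals of 9.14, 16.2 and 6.89, near background. EXPA15, an expansin, fell by 0.74 (SE 0.08), AT3G44450 by 0.71 (SE 0.09) and the thionin gene THI2.2 by 0.7 (SE 0.12). The other named falls were AT1G79770 at -0.94, ASPGB1 at -0.93, AT4G16610 at -0.9, AT5G63460 at -0.88 and AT3G53980 at -0.68. Of the 10 fits that left out 1 array, AT1G79770 and AT4G16610 lost their call in 8, AT1G04660 in 5, ASPGB1, AT5G63460 and THI2.2 in 4 and ZCF37 in 3. The total of 364 was 141 without control replicate 1, 146 without control replicate 2, 102 without 12 hr replicate 1 and 120 without 12 hr replicate 2.

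Early defence and touch genes shifted upwards at 12 hr with 3 of 24 higher, which were AT4G27280, STZ at 1.48 (SE 0.13) and CML38 at 1.17 (SE 0.2), and 21 that did not pass (adjusted p = 1.21e-06, and adjusted p = 0.114 with an estimated correlation). Of 12 jasmonate output genes 2 rose, JRG21 by 1.52 (SE 0.16) and the plant defensin gene PDF1.2 by 1.13 (SE 0.23), and 10 did not pass (adjusted p = 0.000204, and adjusted p = 0.134 with an estimated correlation). Of 11 flavonoid genes 1 fell, the anthocyanin glucosyltransferase gene AT4G14090 by 0.53 (adjusted p of the list = 0.000571, and adjusted p = 0.132 with an estimated correlation). Of 8 glucosinolate genes 1 rose, UGT74B1, a glucosyltransferase of glucosinolate synthesis, by 0.57 (SE 0.09). The glucosinolate list (adjusted p = 0.00515, and adjusted p = 0.142 with an estimated correlation) lost its call without control replicate 2 (adjusted p = 0.0727). When 1 array at a time was left out, PDF1.2 lost its call in 6 of 10 fits, CML38 and AT4G14090 in 4 and UGT74B1 in 3.

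Of 43 plastid-encoded photosynthesis genes 3 rose at 12 hr, ndhF by 1.4 (SE 0.29), psbT by 1.08 (SE 0.21) and atpI by 0.88 (SE 0.15), and 40 did not pass. The upward shift (adjusted p = 0.0296, and adjusted p = 0.326 with an estimated correlation) was not called by fry (adjusted p = 0.125), without control replicate 2 (adjusted p = 0.149) or without 12 hr replicate 1 (adjusted p = 0.457). Of 19 plastid genes of transcription and translation 0 passed by limma, either over all probe sets or over the list alone, with 7 at an unadjusted p below 0.05, though the list shifted upwards (adjusted p = 0.00243, and adjusted p = 0.154 with an estimated correlation). That shift was not called by fry (adjusted p = 0.0711) or without 12 hr replicate 1 (adjusted p = 0.0667). Among these genes, ndhF lost its call in 7 of the 10 fits without 1 array, psbT in 4 and atpI in 3. The control probe sets for 5S and 25S rRNA stood at 0.52 and -0.05 at 12 hr (adjusted p = 0.597 and 0.851). Of 11 clock output genes 1 rose, AT4G33980 by 0.86 (SE 0.18), a call lost in 8 of the 10. The clock list (adjusted p = 0.0402, and adjusted p = 0.216 with an estimated correlation) was not called by fry (adjusted p = 0.0512), without the lowest 30% of probe sets (adjusted p = 0.0846), or without control replicate 1 (adjusted p = 0.151), control replicate 2 (adjusted p = 0.0531) or 12 hr replicate 1 (adjusted p = 0.279).

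After 24 hr 163 probe sets were higher and 55 lower, 53 and 5 of them by at least 2-fold. STZ rose from 241 ± 15.3 to 869 ± 21.3 (SD, n = 2 each; log2 fold change 1.79, SE 0.13, adjusted p = 4.91e-05). AT4G16447 was 4.82-fold, AT4G27280 3.88-fold, AT1G23390 3.57-fold and AT3G15450 3.25-fold above the control. AT1G04660, AT1G33055 and ZCF37 rose to signals of 79.5, 84.9 and 96.5, from the control signals near background given for 12 hr. Among the falls were BZIP17, a membrane-bound transcription factor of the stress response, at -0.74 (SE 0.15), the plastid genes petA at -0.68 (SE 0.1) and psbK at -0.58 (SE 0.11), and AT3G44450 at -0.7 (SE 0.09). The remaining named falls were AT1G57590 at -0.9, AT1G63640 at -0.72, AT2G37870 at -0.7 and AFR at -0.6. Of the 10 fits that left out 1 array, AT1G57590 lost its call in 10, BZIP17 and AT2G37870 in 8, psbK in 6, AT1G63640 and AFR in 5, AT1G04660 in 4, ZCF37 in 3, petA in 2 and AT3G44450 in 1. The total of 218 was 82 without control replicate 1, 70 without control replicate 2, 126 without 12 hr replicate 1, 127 without 12 hr replicate 2 and 96 without 24 hr replicate 1.

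Early defence and touch genes shifted upwards at 24 hr with 3 of 24 higher and 21 that did not pass (adjusted p = 6.16e-05, and adjusted p = 0.129 with an estimated correlation). PDF1.2 rose by 1.68 (SE 0.23) and was the 1 of 12 jasmonate output genes that passed, in a list that shifted upwards (adjusted p = 0.000598, and adjusted p = 0.142 with an estimated correlation). CML38 lost its call in 8 of the 10 fits without 1 array and PDF1.2 in 3. Of 11 clock output genes 1 rose, COR27 by 0.53 (SE 0.09), a call lost in 5 of the 10. The clock list (adjusted p = 0.0122, and adjusted p = 0.149 with an estimated correlation) lost its call without control replicate 1 (adjusted p = 0.0752) and without 24 hr replicate 2 (adjusted p = 0.0884). Over all times, camera called 23 of 108 tests of the 27 further lists, and 20 of the 23 were also among the 34 that fry called. Camera with an estimated correlation called 0, with 21 tests at an unadjusted p below 0.05. That form tests on 5 residual degrees of freedom, which limits what it could call over 108 tests. For early defence and touch genes at 6 hr the camera p rose from 6.66e-11 to 0.00105, though the estimated correlation of 0.006 lay below the preset 0.01. Jasmonate output genes had an estimate of 0.03 and plastid photosynthesis genes 0.039, above the preset value.

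Contrasts between successive times did not use the control means. From 3 to 6 hr 1173 probe sets rose and 907 fell, led by AT3G15450 at 2.94 (SE 0.11) and AT1G23390 at 2.58 (SE 0.09) on the log2 scale and by AT1G33055, from a signal of 8.9, near background, to 142. AT3G51450 fell by 1.94 (SE 0.16), AT2G34930 by 1.68 (SE 0.21) and AT1G54020 by 1.65 (SE 0.16). Scaling to a common median gave 965 higher and 1337 lower. The 2080 calls became 1167 without 3 hr replicate 1, 1199 without 3 hr replicate 2, 959 without 6 hr replicate 1 and 1126 without 6 hr replicate 2.

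From 6 to 12 hr 162 probe sets rose and 381 fell. The plastid genes rps14, ndhF and petG rose by 1.53 (SE 0.11), 1.39 (SE 0.29) and 1.36 (SE 0.16), while JRG21 fell by 2.04 (SE 0.16), COR15A by 2.01 (SE 0.15) and AT5G05600 by 1.61 (SE 0.09) on the log2 scale. Without 1 array ndhF lost its call in 3 of the 10 fits. The 543 calls became 174 without 6 hr replicate 1, 209 without 6 hr replicate 2, 152 without 12 hr replicate 1 and 146 without 12 hr replicate 2.

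From 12 to 24 hr 5 probe sets rose and 21 fell. AT3G28220 dropped by 1.36 (SE 0.17), AT1G66100 by 1.35 (SE 0.14) and AT5G05600 by 1.09 (SE 0.09), while FEY rose by 0.65 (SE 0.1) and AT1G73120 by 0.49 (SE 0.07). The calls of FEY and AT1G73120 were lost in each of the 10 fits that left out an array, and those of AT3G28220 and AT1G66100 in 2. The 26 calls became 14 without either control, 12 without any 1 of the 3 hr and 6 hr arrays, 6 without 12 hr replicate 1, 2 without 12 hr replicate 2, 12 without 24 hr replicate 1 and 65 without 24 hr replicate 2.

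Known root targets and partners of SHR were examined first among the fixed lists. Of 13 members 4 were measured, and 0 passed at any time by limma, over all probe sets or adjusted over the list alone. At an unadjusted p below 0.05, 1 of the 4 stood out at 6 hr and 0 at the other times. JKD, a zinc-finger partner of SHR in the root, stood at -0.35, 0.15, 0.48 and -0.49 (SE 0.43) at 3, 6, 12 and 24 hr, with low signals. The GRAS gene AT5G41920, also called SCL23, stood at 0.15, 0.32, -0.03 and 0.03 (SE 0.14), SLY2 at 0.1, -0.01, -0.12 and 0.42, and TRI at -0.11, -0.3, 0.03 and -0.29 on the log2 scale.

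Only 3 of the 25 fixed lists had 5 or more measured genes, and camera called 0 of their 12 tests, as did camera with an estimated correlation and fry. At an unadjusted p below 0.05, camera had 2 of the 12, fry 2 and camera with an estimated correlation 0. Of 5 measured gibberellin genes the receptor genes GID1A and GID1B rose at 3 hr, by 0.49 (SE 0.12) and 0.93 (SE 0.17), and at 6 hr, by 0.44 and 0.62, and 2 were also called adjusted over the list alone at each time (adjusted p of the list = 0.13 at both). Without 1 array, GID1A lost its call in 5 of the 10 fits at 3 hr and 6 at 6 hr, and GID1B in 1 and 8. Of 6 auxin genes WES1, which conjugates auxin to amino acids, rose by 0.56 (SE 0.1) at 6 hr, a call lost in 2 of the 10 fits, where 1 rose and 1 fell adjusted over the list alone, and the list had adjusted p = 0.952 with a median of -0.1 and a mean of -0.09 against an upward direction of the test. At 12 hr 0 auxin genes passed over all probe sets, 1 was higher and 1 lower adjusted over the list alone, and the mean of -0.09 and median of 0.12 differed in sign. Of 5 genes of the INDETERMINATE DOMAIN family 0 passed by limma over all probe sets, with 1, 1, 0 and 2 at an unadjusted p below 0.05 at 3, 6, 12 and 24 hr, and 1 was higher adjusted over the list alone at 3 hr (adjusted p of the list = 0.438).

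Few genes of the other fixed lists were measured. By limma 0 passed at any time, over all probe sets or the list alone, of 2 genes each for S phase, CDK inhibitors, vascular tissue and heat shock, 3 for stomata and epidermis, and 1 each for the Casparian strip and suberin, leaf growth and salicylate. At an unadjusted p below 0.05, 1 stomata and epidermis gene stood out at 3 hr, 1 at 6 hr and 0 of the others. GI, the 1 measured evening clock gene, did not pass over all probe sets (adjusted p = 0.0673 at 3 hr, and 0.0374 with the arrays scaled to a common median). By limma its unadjusted p was 0.00659 at 3 hr and 0.0447 at 12 hr, higher at both, and with 1 measured gene the list gives no adjustment of its own. Of 3 measured touch and early stress genes 1 rose at 3 hr, 3 at 6 hr and 2 each at 12 and 24 hr, with the same numbers adjusted over the list alone. The kinase genes AUR1 and AUR2, which act in mitosis, were the 2 measured members of the list for the G2/M phase. AUR1 fell by 0.38 (SE 0.09) at 3 hr, a call lost in 5 of the 10 fits without 1 array, where 2 were lower adjusted over the list alone, and at 6 hr AUR1 fell by 0.52 and AUR2 by 0.73, with 2 lower adjusted over the list alone. EXPA8, an expansin, fell by 1.38 (SE 0.11) at 3 hr, also passed at 6 hr and was the 1 measured brassinosteroid gene. AKINBETA1, the 1 measured darkness gene, passed at 6 hr and at 12 hr had only an unadjusted p below 0.05, and of 3 root markers 1, EXPA18, fell at 6 hr. RR16, a cytokinin response regulator, fell by 0.91 (SE 0.08) at 3 hr, as did 1 of 2 adjusted over the list alone at 3 and 6 hr. BCAT4, an enzyme of glucosinolate synthesis, fell by 0.82 (SE 0.11) at 3 hr as 1 of 2 measured members, and adjusted over the list alone 1 was lower at 3 and 6 hr and 1 higher at 6 and 12 hr. STZ, CML38 and WRKY53 made up the touch list at 6 hr. PDF1.2 was the 1 measured jasmonate gene of the fixed list and COR15A the 1 of the abscisic acid list, and each passed at the times given above. At 12 hr COR15A, at 0.58, had only an unadjusted p below 0.05. Of 4 nuclear photosynthesis genes of the fixed list 0 passed by limma at any time, but at 6 hr 3 had an unadjusted p below 0.05 and 3 were lower adjusted over the list alone, among them the Rubisco activase gene RCA at -0.35 (SE 0.11).

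The DEX times shared the same 2 control arrays, which by itself makes their fold changes correlate. Of the calls at 12 hr 87.1% were called in the same direction at 6 hr, and of the calls at 24 hr 82.1% were. Between 3 and 6 hr 365 probe sets were higher at both times and 338 lower at both, against 46 and 41.1 for independent calls. The shared calls, higher and lower, numbered 115 and 49 for 3 and 12 hr (independent 11.3 and 3.2), 52 and 23 for 3 and 24 hr (6.4 and 2.4), 257 and 60 for 6 and 12 hr (14.9 and 3.1), 148 and 31 for 6 and 24 hr (8.4 and 2.3), and 126 and 13 for 12 and 24 hr (2.1 and 0.2). With no effect the simulations made 0 shared calls, so as many top probe sets were taken from them in each direction as had been called, a measure chosen after seeing the data. These top probe sets then shared 258 and 248 for 3 and 6 hr, 97.1 and 34.6 for 3 and 12 hr, 66.9 and 27 for 3 and 24 hr, 115 and 35.6 for 6 and 12 hr, 73.4 and 27.4 for 6 and 24 hr, and 34.5 and 7.4 for 12 and 24 hr. They were picked for extreme noise, that of the shared controls included, whereas the calls had passed the threshold. Neither their overlaps nor their shares of signs therefore measure how many of the shared calls the controls made. Of the calls at the later time 81.1%, 79.9%, 70.6%, 98.4%, 97.2% and 97.2% had the same sign at the earlier one in these pairs, against 86.8%, 91.2%, 92.8%, 92%, 93.1% and 93.3% in the simulations. Correlations of fold changes across probe sets, which are not independent replicates, were 0.52 for 3 and 6 hr, 0.47 for 3 and 12 hr, 0.38 for 3 and 24 hr, 0.67 for 6 and 12 hr, 0.54 for 6 and 24 hr and 0.61 for 12 and 24 hr, where shared controls alone gave 0.5. The covariances of the same pairs were 0.074, 0.053, 0.042, 0.078, 0.062 and 0.054, against simulated values of 0.026, 0.026, 0.026, 0.025, 0.026 and 0.025. The covariances exceeded the simulated ones by 0.048, 0.027, 0.017, 0.052, 0.037 and 0.029. Part of the excess of shared calls may come from the shared controls, since a split would leave 1 control array to each time. At all 4 times 47 probe sets were higher, AT2G20670 and AT2G38240 among them, and 8 were lower, AT3G44450, AT4G33040 and AT3G53980 among them.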

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

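The tests of harvest at another time of day and of array scaling for the called plastid genes, set apart from the median of all plastid genes, were chosen only after the result was seen, and for low oxygen the demand that the bound be met by more than the spread was added then. The values of 5S and 25S rRNA were also brought in after the result was seen. The medians of whole lists under other scalings were not among the tests set in advance. The differences between DEX times below stood out because their effects against 0 hr differed in a limma test of the difference itself.

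Between 3 and 6 hr 47 probe sets were called in opposite directions with a called difference, and there were 11 between 3 and 12 hr, 14 between 3 and 24 hr, 4 between 6 and 24 hr and 2 between 12 and 24 hr. Every probe set called in opposite directions had a called difference. Opposite calls against the same control arrays all but ensure this, so the test of the difference adds no support to them. AT5G39520 stood at -1.05 at 3 hr and 0.99 at 6 hr, a difference of 2.04 (SE 0.18, adjusted p = 4.94e-05). AT4G10270 went from -0.44 at 3 hr to 1.22 at 6 hr. AT2G43620 was at 1.37 at 3 hr and -0.41 at 24 hr, and BGLU28, a beta-glucosidase, at 1 and -0.46. Leaving opposite directions aside, the change differed between 3 and 6 hr for 2080 probe sets, between 3 and 12 hr for 1522, between 3 and 24 hr for 2319, between 6 and 12 hr for 543, between 6 and 24 hr for 1500 and between 12 and 24 hr for 26. Leaving out single arrays moved the counts between successive times by over 1.5 times. The lowest were 959 of the 2080 without 6 hr replicate 1, 146 of the 543 without 12 hr replicate 2 and 2 of the 26 without 12 hr replicate 2. Among the 64 control probe sets, which no comparison used, 2 lay above the 0 hr arrays, both for the 5' part of GAPDH at 24 hr (0.34, adjusted p = 0.019). Spike-in control probe sets lay below them, DapX-3 at 6 hr (-0.42, adjusted p = 0.0244) and 24 hr (-0.43, adjusted p = 0.019) and ThrX-3 at 6 hr (-0.52, adjusted p = 0.0247).

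Of 17 cold genes 6 rose at 3 hr and 7 at 6 hr, with 1 lower at 6 hr, and of 12 jasmonate genes 4 and 3 rose (adjusted p with an estimated correlation = 0.129 and 0.132 for cold, 0.142 and 0.134 for jasmonate). Array scaling is argued against by the medians of the whole lists at 3 hr. They were 0.21 for cold and 0.43 for jasmonate as deposited, and 0.22 and 0.47 after quantile normalization. The median of the 10 called genes at 3 hr, 1.49 as deposited and 1.55 after quantile normalization, tests little, since they were picked as higher in these data. For harvest at another time of day, the largest absolute log2 fold changes of 6 genes of high daily amplitude had a median of 0.35. Of the 6, 0 reached 1, which met the bound set against this explanation. It stays open all the same, since that bound was set after the result was seen. The called clock genes AT2G15020, AT4G33980 and COR27 were also not among the 6. The clock output list was called at 12 and 24 hr, though not with an estimated correlation (adjusted p = 0.216 and 0.149) or, at 12 hr, by fry (adjusted p = 0.0512). GI was higher by limma before adjustment, at 3 hr (unadjusted p = 0.00659) and 12 hr (unadjusted p = 0.0447). Over all probe sets it did not pass (adjusted p = 0.0673 and 0.36), though at 3 hr it passed with the arrays scaled to a common median. Handling, solvent or DEX itself may have raised these genes, and this cannot be told apart from SHR-GR induction, the difference that the design names, since 0 mock-treated arrays stand beside the DEX times.

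Of 24 early touch and stress genes 10, 3 and 3 rose at 6, 12 and 24 hr (adjusted p = 0.114, 0.114 and 0.129 with an estimated correlation), and low oxygen during the treatment was weighed because AT1G33055 and CML38 also respond to it. The 15 low-oxygen genes not examined before had a median of 0.09 at 6 hr (bootstrap SD 0.17), with 3 higher and 2 lower, and a median of 0.19 after quantile normalization. Their mean was 0.16, and they shifted upwards by fry (unadjusted p = 0.0234) but not by camera (unadjusted p = 0.111). The bound of 0.1 set in advance for the absence of such a response was met, but by less than that SD, so low oxygen cannot be told apart from other explanations here. The 7 genes seen beforehand had a median of 1.52, which tests nothing because their rise prompted the question. Handling and SHR-GR induction stay open, with no mock-treated arrays to part them.

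Of 69 plastid-encoded genes 22 fell at 6 hr and 1 rose, and array scaling may account for the lower median of all 69, which was -0.19 as deposited and -0.09 after quantile normalization, or -0.06 relative to all probe sets. For the 43 plastid photosynthesis genes among the 69, the median was -0.31 as deposited, -0.32 after quantile normalization and -0.31 with a common median. These scalings therefore did not account for the lower median of the 43. The test set in advance was of all 69, however, and the list of 43 had already been called lower in these data. Of the called genes 21 of 22 stayed lower, which tests little, as they were picked as lower in these data. Lower labelling of all RNA without a poly(A) tail is argued against by the mean of 16 mitochondrially encoded genes, which changed by 0.14 while that of the plastid-encoded genes changed by -0.24, and by 25S rRNA at 0, but 5S rRNA stood at -0.45 (adjusted p = 0.168), so such an effect on part of this RNA stays open. More degraded RNA at 6 hr than at 0 hr is argued against, as the largest rise among the mean 3' to 5' ratios of actin, GAPDH and ubiquitin was 0.04, and that of GAPDH changed by -0.18. The log2 ratio of actin was uneven at 6 hr, at 4.75 and 4.16 against 4.54 and 4.36 on the control arrays. These ratios compare the times and do not show that the RNA was intact. Time of day, handling and SHR-GR induction stay open, and no mock-treated array tests them.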

How the results depend on the processing

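The alternatives for the further lists and the leaving out of single arrays for both kinds of list were chosen after seeing the data. Other alternatives were planned.

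Counts moved by over 1.5 times as follows, and the cause was not tested except where fewer probe sets or arrays were used. Leaving out the lowest 30% of probe sets gave 552 calls at 12 hr, 393 at 24 hr and 50 from 12 to 24 hr, and leaving out the lowest 50% gave 358 at 24 hr and 56 from 12 to 24 hr, with fewer probe sets to adjust for. Variance moderation without the intensity trend gave 937, 1216, 129 and 58 at 3, 6, 12 and 24 hr, 1099, 177 and 1 between successive times and 1298 at any time. Array weights gave 141 at 24 hr and 850 from 6 to 12 hr. A fit of only the 4 arrays compared gave 1022 at 3 hr, 49 at 24 hr, 1239 from 3 to 6 hr and 1 from 12 to 24 hr, with 2 residual degrees of freedom. Asking for a log2 fold change of at least 1 gave 267, 395, 98 and 58 at the 4 times and 366, 96 and 6 between them, which is a stricter demand by construction. Leaving out 1 array, whose partner is then assumed to vary like the other groups, gave 866 to 2035 at 3 hr, 989 to 2297 at 6 hr, 102 to 414 at 12 hr, 70 to 192 at 24 hr, 959 to 2245, 146 to 591 and 2 to 65 between successive times, and 1940 to 3244 at any time.

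Under the offsets of 1 and 64, quantile normalization, a common median and a robust trend, each of these counts stayed within 1.5 times of its value. Only the offsets, quantile normalization, the common median and leaving out a compared array could alter a fold change, so elsewhere no direction could change. Of 238 called values of named genes, the alternatives gave 5183 values, of which 4326 kept their call, 857 lost it and 0 changed direction. Moderation without the trend accounted for 94 of the losses, the demand for a log2 fold change of at least 1 for 129, the 4 arrays compared for 69 and single arrays left out for 497. Of 188 values that did not pass, 15 passed under some alternative. The fixed lists gave 0 calls by camera under every alternative run, with 2 of 12 tests at an unadjusted p below 0.05 and 0 calls by fry, and the further lists gave 0 calls with an estimated correlation.

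With the replicate number as a replicate block the count from 12 to 24 hr became 14, no other count moved by over 1.5 times, and 22 of the 238 called values of named genes lost their call. The paired check over 10 pairs of groups gave correlations from -0.04 to 0.09, none above 0.1, so the numbers were not treated as pairs.

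Signals near the background limit what low probe sets can show, JKD and BSMT1 among them, as they lay below a mean signal of about 43.4.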

Other observations

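The lists in this part were built after gene names were seen and before groups were compared, and camera was fixed then, whereas fry and the fits without 1 array were chosen for them after seeing the data.

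Expansins and other wall-loosening genes moved in both directions without a call of their list. Of 28 measured genes 3 rose and 4 fell at 3 hr, with EXPA16 at 2.04 (SE 0.24), EXLA1 at 0.86 (SE 0.15), EXPA8 at -1.38 (SE 0.11) and EXPB3 at -0.82 (SE 0.08), and 4 rose and 7 fell at 6 hr, with EXGT-A3 at 1.21 (SE 0.08) and EXPA15 at -0.99 (SE 0.08). The list had adjusted p = 0.607 at 3 hr and 0.891 at 6 hr by camera. Of 19 sugar transporter genes 2 rose and 1 fell at 3 and at 6 hr. SWEET13, a sucrose exporter, fell by 1.01 (SE 0.11) at 3 hr and by 0.94 (SE 0.11) at 6 hr, while SWEET4 rose by 0.94 (SE 0.18) at 3 hr (adjusted p of the list = 0.318 and 0.998). Of 22 trichome birefringence-like genes, which act in wall acetylation, 2 rose and 5 fell at 3 hr, with TBL26 at 1.31 (SE 0.13) and TBL36 at -1.53 (SE 0.15), and the list had adjusted p = 0.391 by camera, while fry called it lower (adjusted p = 0.0317).

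Of 14 iron genes 4 rose and 1 fell at 6 hr, and 2 rose at 12 and at 24 hr. BHLH101, a transcription factor of the iron deficiency response, stood at 1.86 (SE 0.23) at 6 hr, 1.15 at 12 hr and 1.39 at 24 hr, and AT5G05250 at 0.91 (SE 0.11), 0.82 and 1.06, from a control signal of 42.8 for BHLH101, near background. Without 1 array BHLH101 lost its call in 7 of the 10 fits at 12 hr and in 3 at 24 hr, and AT5G05250 in 1 at 12 hr. Camera did not call the list (adjusted p = 0.245, 0.0849 and 0.0585), while fry called it higher at each of these times (adjusted p = 0.0317). Of 14 heat response genes 2 rose and 1 fell at 3 and at 6 hr. The small heat shock protein genes AT1G53540 and AT2G29500 rose at 3 hr, by 1.93 (SE 0.25) and 1.8 (SE 0.16), and at 6 hr, by 2.25 and 1.54, while Fes1C fell by 0.37 (SE 0.09) at 3 hr, a call lost in 8 of the 10 fits without 1 array, and Hsp70-2 by 0.6 (SE 0.1) at 6 hr (adjusted p of the list = 0.245 and 0.607, and fry called it higher at 3 hr with adjusted p = 0.0317). The control signal of AT1G53540 was 27.1, near background. Of 23 cell division genes 2 fell at 3 hr and 4 at 6 hr, AUR1, AUR2, 3xHMG-box2 and UBC20, and 0 passed at 12 and 24 hr by limma (adjusted p of the list = 0.0849 and 0.079 at 3 and 6 hr by camera). Fry called the list lower at 3 hr (adjusted p = 0.0183) and 6 hr (adjusted p = 0.0138). Of 12 autophagy genes 3 fell and 0 rose at 3 hr, APG8A by 0.48, ATG8C by 0.38 and ATG8F by 0.35 (adjusted p of the list = 0.0849 by camera and 0.0523 by fry), calls lost in 5, 3 and 6 of the 10 fits without 1 array. Of the same genes ATG8E rose by 0.92 (SE 0.14) at 6 hr and ATG8C fell by 0.41 (SE 0.08), with adjusted p = 0.967 for the list by camera. NRT2.5 and EXPA18 were the 2 of 11 root marker genes that fell at 6 hr, and CSLD2 rose by 0.38 (adjusted p of the list = 0.466 by camera, and 0.0317, lower, by fry). Without 1 array CSLD2 lost its call in 8 of the 10 fits, UBC20 in 4, ATG8C in 3 and 3xHMG-box2 in 2 at 6 hr, and AUR1 in 5, 3xHMG-box2 in 3 and SWEET4 in 2 at 3 hr.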
